A study of Mus musculus with 14 samples.

How the data were processed

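Gene expression was measured by bulk RNA sequencing in 14 libraries of cells sorted from mouse bone marrow. Per the labels, total RNA was purified with a column kit for small samples and made into libraries after depletion of ribosomal RNA. The values used are CPM per gene (reads or fragments scaled to a common library total), which the authors deposited under the name FPKM in 2 tables, 1 for dendritic cells (24980 genes) and 1 for monocytes and macrophages (17118 genes, all of them also in the first). Per the submitters' processing notes, the genome build was mm10 and the tools were STAR 2.5.3a and Partek, whose roles are not given in the sources used here. The gene annotation, the setting for strand and the filter behind the smaller table are not given either, so overlapping or antisense genes cannot be told apart and near-identical family members (such as the globin and histone genes) are uncertain. The tables hold no exact 0, and the lowest value in either is 0.0001, which appears to have been added to every value. No symbol was repeated and 0 pairs of libraries held identical values.

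The unit was read from the values, against the name. Less 0.0001, the low values of each library lay for the larger part on whole multiples of 1 step that was the same for short and long genes, whereas the step of FPKM depends on the length of the gene. Within 0.05 steps of a whole multiple lay 65.8% to 68.7% of the values up to 50 steps in the dendritic cell libraries and 87.6% to 90.5% in the monocyte and macrophage libraries, against at most 12.2% with a step 7% longer. In the dendritic cell table the share was 75.9% to 80.1% in the third of genes with the shortest genomic span and 57.9% to 60.5% in the third with the longest. In the other table it was 85.7% to 89.8% and 90.9% to 92.9%. Values were therefore not divided by gene length, and levels of different genes compare reads, not transcripts. Log2 changes, tests and calls within a gene are those of the values as deposited. The design, the alternatives and the filter had been written for FPKM, the tests had been run when the unit was corrected, and the same limma test serves for CPM.

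If 1 step is 1 read or fragment, 1 CPM stood for 71.6, 37.9, 39.1 and 59.8 of them with vehicle, 63.4, 28.2, 30.3 and 65.3 with PAM3CSK4, 56.5, 49.9 and 53.3 in monocytes and 33.4, 68.2 and 75.2 in macrophages. These numbers follow the depth of the libraries, and their ranges overlap between the groups of each comparison. The filter at 1 CPM thus lay at 28.2 to 75.2 reads or fragments. The values of a library summed to between 350368 and 578711, so the listed genes held 35.0% to 57.9% of what the scaling counted. Of all values above the lowest, 53.5% to 55.4% came out whole in the dendritic cell libraries and 79.9% to 83.9% in the others. That is too few to take the values back to counts, so no count test was made.

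Groups were taken from the sample labels, and the replicate numbers from the sample titles. A further 3 columns of the monocyte and macrophage table have names that point to dendritic cells but give no treatment and match no single sample by name. Their steps equal those of vehicle replicates 1, 2 and 3 to within 0.001%, while the next nearest library differed by at least 3.13%, so they appear to be those libraries with reads assigned to genes in another way. They were not used, because the planned test asked for columns that match by name. The labels do not say whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical in part. The dose, the time between dose and collection, and the number and sex of the mice are not given in the labels.

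Differences were tested within each table with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) on log2(CPM + 1), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes below come from this test. A gene was tested if it reached 1 CPM in at least as many libraries as the smaller group holds, which was 4 for dendritic cells and 3 for macrophages against monocytes. Log2 changes are on the log2(CPM + 1) scale and understate the change of genes with low values. Dendritic cells were not tested against monocytes or macrophages, because no single table holds columns of these groups that match by name. The tables also appear to differ in how reads were assigned to genes.

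Before the data were examined, 34 gene lists of pathways, cell types and quality measures were fixed, together with the tests, the alternatives and the rule for the genes named. The text names the 8 largest rises and 8 largest falls in log2 change among genes past the threshold whose groups did not overlap, with a mean of at least 5 CPM in the higher group and an assigned symbol, up to 4 members of each list in order of unadjusted p, and the genes of the sorting markers and of the receptor of the agonist. Other genes named were chosen after their values were seen and are said to be. Lists with at least 3 measured members (33 of the 34) were tested with limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were the alternatives. A list of mitochondrially encoded genes had 0 measured members.

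The methods were tested on simulated data with the means and spreads of the real genes and 200 changed genes. For dendritic cells (11377 genes), 32.8% of genes changed 2-fold, 86.6% of those changed 4-fold and 98.5% of those changed 8-fold were recovered, with 7 wrong calls among 152. For macrophages against monocytes (12188 genes), the shares were 5.97%, 73.1% and 87.9%, with 1 wrong call among 112. The real comparisons called more genes than the 200 simulated (582 and 2468). The adjustment depends on the share of genes changed, so recovery in the real data may differ. The simulated genes were independent of each other, so a shifted list was found by camera with either correlation and by fry. Alternatives were other pseudocounts (0.1 and 5), no filter and a filter at 5 CPM, rescaling each library to a common total, median centring, quantile normalization, limma without a trend or with robust estimation, array weights, the replicate number as a block, a 2-fold threshold, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.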

Results

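The libraries were made from 3 populations sorted by flow cytometry from the bone marrow of mice that carry a GFP reporter in 1 copy of the gene of the chemokine receptor CX3CR1. Dendritic cells, which present antigen to T cells, were sorted as cells high in GFP, MHC class II and CD11c and without Gr-1 and B220. Macrophages were GFP-negative, high in MHC class II and CD169-positive, also without Gr-1 and B220, and monocytes were GFP-high and CD115-positive without B220, with low and high Gr-1 together. Dendritic cells came from mice given vehicle (4 libraries) or a single dose of PAM3CSK4 (4 libraries), a synthetic lipopeptide that activates Toll-like receptor 2 together with Toll-like receptor 1. Monocytes (3 libraries) and macrophages (3 libraries) were collected at baseline. Values are CPM, reads scaled to the library total without division by gene length. Genes that encode the sorting markers were held up or down by the gates that used them, and are not findings between populations there. CD115 was asked for in the monocyte gate only, and CD169 and MHC class II were not part of that gate. The comparisons ask how dendritic cells respond to the agonist and how the baseline populations differ.

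Among the genes named by size of change in dendritic cells after PAM3CSK4, Cd209a fell most and Saa3 rose most. Cd209a (chromosome 8, 3743395 to 3748984 in mm10), a C-type lectin of dendritic cells and monocytes, was at 391 ± 49.9 CPM (SD, n = 4) with vehicle and 3.12 ± 4.40 CPM with PAM3CSK4, a log2 change of −7.12 ± 0.54 (SE) with adjusted p = 3.7e-05. The lectins Mgl2 (chromosome 11, 70130357 to 70137542) and Clec10a (chromosome 11, 70166623 to 70170836) had log2 changes of −5.60 ± 0.42 and −4.27 ± 0.42. Saa3 (chromosome 7, 46711998 to 46715676), an acute-phase protein, rose from 0.0704 ± 0.141 to 258 ± 272 CPM (log2 change 6.98 ± 0.84, adjusted p = 0.0011), and the scavenger receptor Marco (chromosome 1, 120474538 to 120505024) rose from 0.810 ± 0.640 to 77.8 ± 41.9 CPM (log2 change 5.20 ± 0.52, adjusted p = 0.00035). The calls of these 5 genes held with any 1 library left out and under every other setting tried.

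Among the other largest changes, the Fc receptor-like gene Fcrl5 rose by 4.56 ± 0.52 on the log2 scale, Ly6d by 3.94 ± 0.64, the dicarboxylate transporter Slc13a3 by 3.83 ± 0.56, the complement gene Cfb by 3.75 ± 0.63 and the formyl peptide receptor Fpr1 by 3.72 ± 0.60. Lipg, an endothelial lipase, rose by 3.75 ± 0.90, but its call was lost with any of 6 of the 8 libraries left out (adjusted p up to 0.11). Trf (transferrin) fell from 407 ± 41.5 to 24.0 ± 7.55 CPM, the prostaglandin-degrading enzyme Hpgd from 58.6 ± 14.8 to 2.73 ± 1.75 CPM and the mannose receptor Mrc1 from 234 ± 40.8 to 25.7 ± 26.5 CPM. Cd209c fell by 3.73 ± 0.34 and Abca6 by 3.55 ± 0.41 on the log2 scale. The calls of Ly6d, Cfb, Fpr1 and Mrc1 were lost with no filter on low values (adjusted p up to 0.068).

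**Figure D1:**
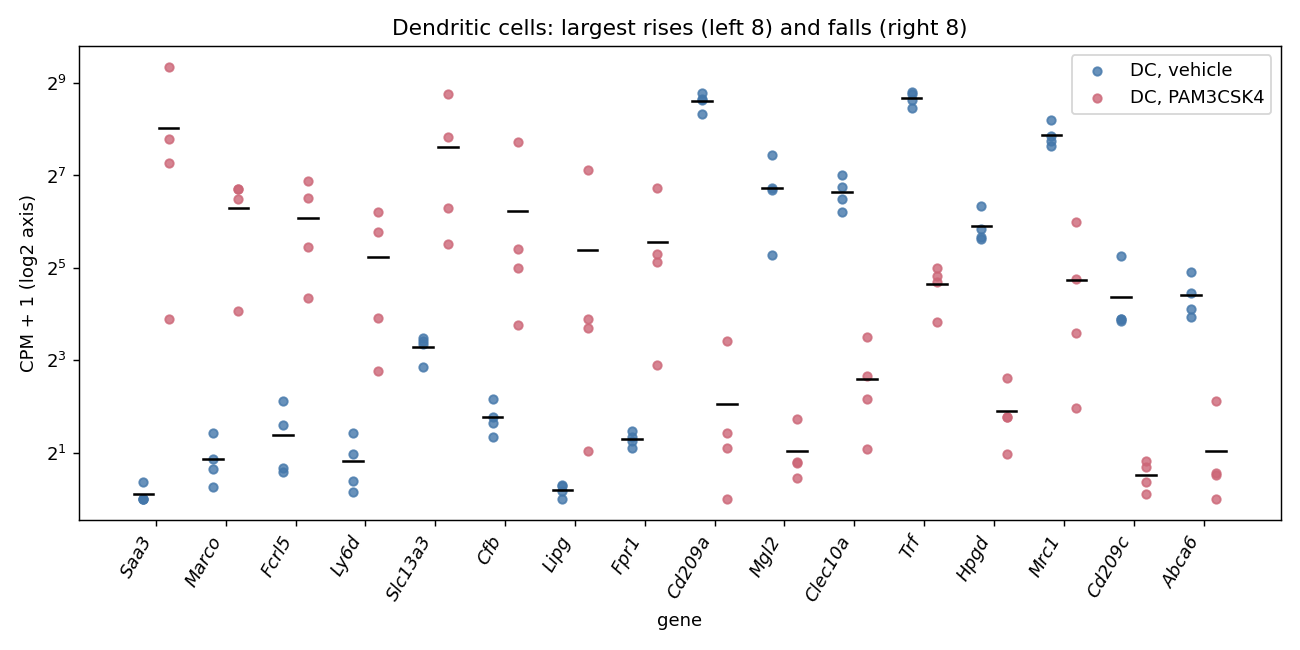
CPM plus 1 (log2 axis) of the 8 genes with the largest rises and the 8 with the largest falls in dendritic cells, 1 point per library (4 with vehicle, 4 with PAM3CSK4), with a bar at the mean CPM plus 1. The groups do not overlap for any of the 16 genes, which were chosen so.

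Of 11377 genes tested, 582 changed, of which 321 rose and 261 fell, and 507 changed at least 2-fold. The median log2 change of all genes was 0.20, so the split between rises and falls depends on the scaling: 55.2% of calls were rises as deposited, 41.6% after rescaling each library to a common total, 29.9% after median centring and 35.1% after quantile normalization, where the median log2 change of all genes was 0.08, −0.02 and 0.02. The groups did not overlap for 14.8% of the genes tested, where chance gives 2.86%. The count fell to 206, 184, 226 and 261 without vehicle replicates 1, 2, 3 and 4 and to 258 without PAM3CSK4 replicate 3, rose to 1008 without PAM3CSK4 replicate 1, and was 166 with no filter on low values. The share of rises moved with single libraries too: it was 27.7% without vehicle replicate 1 (57 rose, 149 fell), 41.3% and 42.5% without vehicle replicates 2 and 3, and 36.4% without PAM3CSK4 replicate 3 (94 rose, 164 fell).

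PAM3CSK4 replicate 4 stood apart from the other 7 libraries. Correlations of log2 values were 0.946 to 0.971 among vehicle libraries and 0.879 to 0.961 among PAM3CSK4 libraries. Those of PAM3CSK4 replicate 1 were 0.923 to 0.939 with vehicle libraries and 0.938, 0.955 and 0.879 with PAM3CSK4 replicates 2, 3 and 4. The label of replicate 1 was not tested. Replicate 4 held 27.5 CPM of Itgax (CD11c), where the other PAM3CSK4 libraries held 278, 181 and 283, and 31.3 CPM of Cx3cr1, where they held 154, 209 and 152. It held 1317 CPM of Lcn2 and 1962 of Ltf, both neutrophil granule genes, against at most 163 and 264 in the other PAM3CSK4 libraries. Without it, 785 genes changed (463 rose, 322 fell), 506 of them also among the 582. Over all 8 libraries, the log2 changes of Itgax (−0.69 ± 0.59) and Cx3cr1 (−0.39 ± 0.48) did not pass (adjusted p = 0.49 and 0.64), and without replicate 4 they were 0.09 and 0.21. Csf1r (−0.66 ± 0.34), Ptprc (0.37 ± 0.35) and Ly6c2 (0.59 ± 0.60) did not pass either, nor did Siglec1 (−1.66 ± 0.49, adjusted p = 0.069), which passed after each of the 3 rescalings and without PAM3CSK4 replicate 2.

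Some antigen presentation and dendritic cell identity genes fell. In the list of conventional dendritic cell identity, 5 of 23 measured members fell and 0 rose, or 8 fell adjusted over the list alone. The 5 include Cd209a, Mgl2 and Clec10a, the lectins given above among the largest falls, so the count is not separate from them. Another was the transcription factor Zbtb46, which fell by 1.68 ± 0.39 on the log2 scale with all libraries. Zbtb46 did not pass with any 1 of 6 libraries left out (adjusted p up to 0.092). In the MHC class II list, 1 of 14 members passed (H2-DMa, log2 change −1.60 ± 0.40), 9 fell and 1 rose adjusted over the list alone, and H2-Ab1 was at 2504 ± 523 CPM with vehicle and 885 ± 504 CPM with PAM3CSK4 (adjusted p = 0.064). Without PAM3CSK4 replicate 4, which was low in both lists, 8 of the 14 MHC class II members fell and 2 rose, and H2-Ab1 passed with a log2 change of −1.16 (adjusted p = 0.016). The call of H2-DMa was lost with any of 5 libraries left out (adjusted p up to 0.11). Camera placed both lists below the other genes (adjusted p = 3.5e-11 and 1.1e-06), but not with an estimated correlation (adjusted p = 0.61 for each).

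Inflammatory and feedback genes rose in part. Of 20 TLR-induced effectors, 5 rose and 0 fell (6 rose and 1 fell adjusted over the list alone), including the ectoenzyme Cd38 (log2 change 3.43 ± 0.55) beside Saa3, Marco and Fpr1. Lcn2, also in the neutrophil list, did not pass. The mean log2 level over all 24 listed effectors was 1.94 to 2.20 with vehicle and 2.32, 4.11, 3.69 and 4.46 in PAM3CSK4 replicates 1 to 4. For this list camera gave adjusted p = 0.0013, and adjusted p = 0.67 with an estimated correlation. The feedback inhibitors Socs3, of cytokine signalling, and Irak3, of Toll-like receptor signalling, rose by 3.06 ± 0.53 and 2.45 ± 0.44. With no filter on low values the calls of Cd38, Socs3 and Irak3 were lost (adjusted p = 0.061, 0.069 and 0.069). Of 25 NF-kB pathway genes 2 rose (Socs3 and Tnip1) and 0 fell, or 3 rose adjusted over the list alone, and the call of Tnip1 was lost with any 1 of 6 libraries left out (adjusted p up to 0.13). Of 24 TLR signalling components 1 rose (Irak3) and 2 fell (Tlr3 and Irak2), with the same counts adjusted over the list alone. The call of Tlr3 was lost without vehicle replicate 2 or 3 (adjusted p = 0.063 and 0.064) and that of Irak2 with any 1 of 6 libraries left out (adjusted p up to 0.12). Of 10 measured cytokine genes 1 rose, Il1b (log2 change 2.11 ± 0.51, adjusted p = 0.035), and it did not pass after any of the 3 rescalings or with any 1 of 6 libraries left out (adjusted p up to 0.13 over all settings). The mean log2 level over all 20 listed cytokine genes, tested or not, was 1.49 in PAM3CSK4 replicate 1, within the vehicle range of 1.47 to 1.70. It was 2.10 to 2.36 in the other PAM3CSK4 libraries. Without replicate 1, Tnf (log2 change 1.57, adjusted p = 0.0029) and Il1rn (2.00, adjusted p = 0.038) passed. Of 10 chemokine genes, Ccl2 rose and Ccl6 and Ccl9 fell, by 1.94 ± 0.31 and 1.70 ± 0.28 (3 rose and 2 fell adjusted over the list alone), and the call of Ccl2 was lost with any 1 of 5 libraries left out (adjusted p up to 0.14). The median change of the chemokine list was 0.07 and turned negative after median centring. The receptor genes did not pass, with log2 changes of 0.70 ± 0.39 for Tlr1, −0.28 ± 0.26 for Tlr2, 0.08 ± 0.30 for Tlr6 and 0.64 ± 0.24 for the adaptor Myd88. Of 37 interferon-stimulated genes 0 passed in limma, while 1 was higher and 7 were lower at an unadjusted p under 0.05. Camera placed this list below the other genes (adjusted p = 0.00090, and adjusted p = 0.67 with an estimated correlation).

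In the list of dendritic cell maturation genes, 1 of 22 rose with all libraries, the checkpoint ligand Cd274 (log2 change 2.23 ± 0.45), and 4 rose adjusted over the list alone. Without PAM3CSK4 replicate 4, 10 of the 22 rose. The call of Cd274 was lost with any 1 of the 4 vehicle libraries left out (adjusted p up to 0.061), and the list did not pass camera (adjusted p = 0.30).

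Genes of macrophages and of iron handling went both ways. Of 23 macrophage markers, 4 rose and 6 fell (7 and 7 adjusted over the list alone), with Cd163, the haemoglobin scavenger receptor, down by 3.12 ± 0.32 and the lipid carrier Apoe by 2.96 ± 0.36 on the log2 scale. Of 19 iron and heme genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone). The macrophage and iron lists share members, among them Cd163, counted as a fall in both, and Hmox1, counted as a rise in both. The transferrin receptor Tfrc rose by 2.26 ± 0.28 while Trf fell, and the heme-degrading enzyme Hmox1 rose by 2.26 ± 0.45, a call lost without vehicle replicate 1, 3 or 4 (adjusted p up to 0.062). Of 23 monocyte markers 1 rose and 4 fell (2 and 4 adjusted over the list alone; the median change was 0.10 and turned negative after median centring), including the peptidase Ace (−3.16 ± 0.47) and the chemokine receptor Ccr2 (−1.80 ± 0.31), whose call was lost with no filter on low values (adjusted p = 0.063).

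Of 30 cell cycle genes, 8 rose and 0 fell, and 23 rose adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose by 1.41 ± 0.31 and Pcna, the replication clamp, by 0.88 ± 0.19, calls that were lost with any of 4 and 5 libraries left out (adjusted p up to 0.088 and 0.062). Of 23 immediate early genes 3 fell and 0 rose, led by Btg2 (−1.35 ± 0.23), with 12 fallen and 1 risen adjusted over the list alone. The mean log2 level of the immediate early list overlapped between the groups, with 5.09 in vehicle replicate 3 and 5.47 and 5.35 in PAM3CSK4 replicates 2 and 3. Camera gave adjusted p = 1.5e-08 and 1.1e-06 for the cell cycle and immediate early lists, and adjusted p = 0.61 for each with an estimated correlation.

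Some markers of other cell types also differed between the groups. The mean log2 levels of the neutrophil, erythroid and progenitor lists, over all listed members, overlapped between the groups. They were 4.09, 3.60 and 2.542 in vehicle replicate 4 and 3.75, 2.19 and 2.541 in PAM3CSK4 replicate 1. The erythroid level was 3.49 and 3.13 in PAM3CSK4 replicates 2 and 3. Of 17 neutrophil genes 2 rose (Mmp8 and Csf3r), of 14 erythroid genes 3 rose, including Hbb-bs (log2 change 3.22 ± 0.68), and of 12 progenitor genes 2 rose (Sox4 and Ly6a), with 0 falls in each. Adjusted over the list alone, 9, 7 and 3 rose. Without PAM3CSK4 replicate 4 the counts were 3 risen and 2 fallen for neutrophil, 3 risen for erythroid and 2 risen for progenitor genes. Of 13 plasmacytoid dendritic cell genes 5 rose, with Ly6d first, and 1 fell, Cd209d, and without PAM3CSK4 replicate 4 the counts were 8 and 1. Of 5 megakaryocyte genes 2 fell (Pf4 and Vwf). The calls of Csf3r, Hbb-bs, Sox4, Ly6a, Pf4 and Vwf were each lost with between 3 and 7 of the 8 libraries left out in turn, and that of Mmp8 without vehicle replicate 1 (adjusted p = 0.060). Ly6g, the neutrophil gene whose product Gr-1 antibodies bind, was below the filter, at 2.48 CPM in PAM3CSK4 replicate 4 and at most 0.264 CPM in the other 7 libraries.

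**Figure D2:**
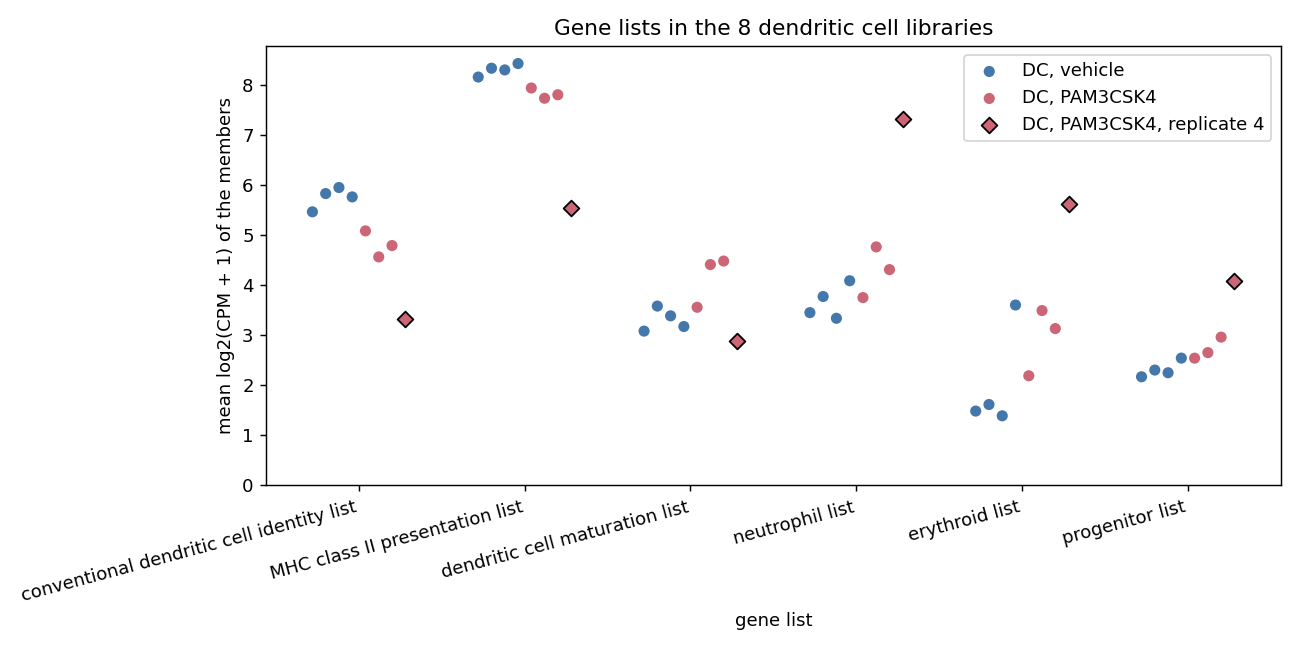
Mean log2(CPM + 1) over the members of 6 gene lists in each of the 8 dendritic cell libraries (blue, vehicle; red, PAM3CSK4; diamond, PAM3CSK4 replicate 4). Replicate 4 is lowest in the dendritic cell identity list (3.32, other PAM3CSK4 libraries 4.56 to 5.08) and highest in the neutrophil list (7.31, others 3.75 to 4.76).

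At baseline, libraries labelled macrophage and monocyte differed in 2468 of 12188 genes tested. The extracellular matrix gene Fn1 (chromosome 1, 71585473 to 71653234) was at 4708 ± 787 CPM (SD, n = 3) in monocytes and 201 ± 152 CPM in macrophages, a log2 change of −4.91 ± 0.54 (SE, adjusted p = 7.9e-05), and the coagulation factor gene F13a1 was at 1485 ± 467 and 65.0 ± 44.9 CPM. The immunoglobulin joining chain gene Jchain (chromosome 5, 88519809 to 88527897), a plasma cell gene, was at 4.06 ± 4.11 CPM in monocytes and 3105 ± 3378 CPM in macrophages (log2 change 8.93 ± 0.90, adjusted p = 4.7e-05), with 2029, 397 and 6891 CPM in the 3 macrophage libraries. Xcr1 (chromosome 9, 123852315 to 123862029), a receptor of cross-presenting dendritic cells, rose by 5.64 ± 0.50, and Hlf, a transcription factor of blood stem cells, by 5.50 ± 0.39. The calls of these 5 genes held with any 1 library left out.

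The other largest rises in macrophages were the plasma cell and B cell genes Mzb1 (5.74 ± 0.73) and Pou2af1 (5.58 ± 0.69), the interleukin 2 receptor gene Il2rb (5.55 ± 0.45) and the lymphocyte GTPases Gimap3 (5.51 ± 0.36) and Gimap4 (5.31 ± 0.38). The other largest falls were Ace (−4.40 ± 0.68), Arhgef37 (−4.28 ± 0.47), Cd209a (−4.21 ± 0.56), the proteoglycan Vcan (−4.17 ± 0.40) and the collagenase Mmp8 (−3.98 ± 0.47). Of the genes of the sorting markers, Cx3cr1 was at 127 ± 70.3 CPM in monocytes and 4.17 ± 2.31 CPM in macrophages. Csf1r (CD115) was at 559 ± 273 and 37.1 ± 14.4 CPM (log2 change −3.83 ± 0.37, adjusted p = 3.5e-05). The macrophage gate did not use CD115, so it did not directly set the low level of Csf1r in macrophages. Ly6c2, bound by Gr-1 antibodies, was at 495 ± 155 and 84.7 ± 51.5 CPM. Ptprc, which encodes CD45 and its form B220, did not pass (−0.42 ± 0.26).

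**Figure D3:**
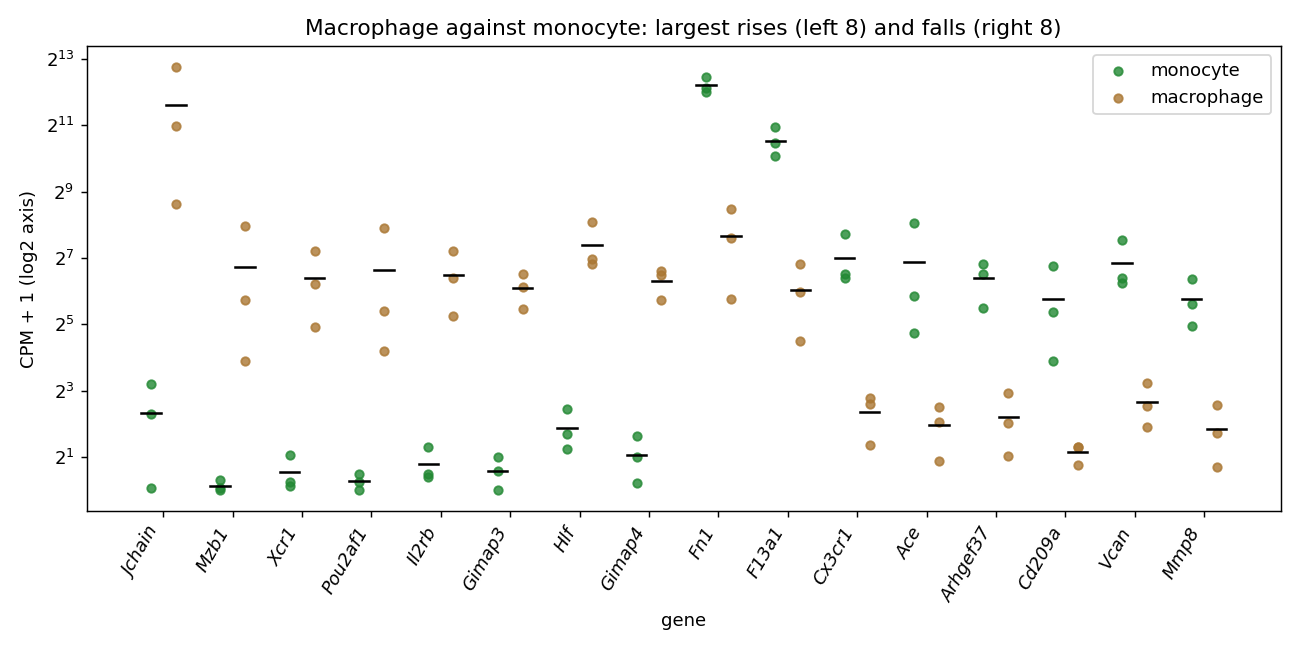
CPM plus 1 (log2 axis) of the 8 genes with the largest rises and the 8 with the largest falls in macrophages against monocytes, 1 point per library (3 of each), with a bar at the mean CPM plus 1. The groups do not overlap for any of the 16 genes, which were chosen so.

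Of the 2468 genes, 1564 were higher and 904 lower in macrophages, and 2172 differed at least 2-fold. Rises made up 63.4% of calls as deposited, 51.3% after median centring, 44.8% after quantile normalization and 72.8% after rescaling to a common total, with a median log2 change of all genes of 0.10, −0.02, −0.03 and 0.27. The groups did not overlap for 34.2% of the genes, where chance gives 10%. The number of lower genes was 537 without macrophage replicate 2.

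Monocyte markers were lower in macrophages: 17 of 24 fell and 0 rose (19 fell adjusted over the list alone). The gates bear on 4 members (Cx3cr1, Csf1r, Ly6c1 and Ly6c2), of which Csf1r through the monocyte gate only. The list was also tested without these 4, a test chosen after seeing the data. Then 14 of 20 fell (15 adjusted over the list alone), and camera gave adjusted p = 7.3e-12. Among the other members were the transcription factor Klf4, down by 3.47 ± 0.25 on the log2 scale, and Ms4a6c, down by 3.32 ± 0.28. With all 24 members camera gave adjusted p = 7.3e-15, and with an estimated correlation adjusted p = 0.25 with or without the 4. Fry, run with all 24 members only, gave adjusted p = 0.015. Of 24 TLR signalling components 2 rose and 11 fell, or 14 fell adjusted over the list alone. Tlr8 and Tlr13, sensors of RNA, fell by 2.98 ± 0.39 and 2.02 ± 0.28, Tlr2 fell by 1.59 ± 0.24, Tlr6 by 1.03 ± 0.30 and Myd88 by 0.89 ± 0.26 (both lost with any 1 of 4 libraries left out), Tlr1 did not pass (−0.93 ± 0.36), and Tlr3, which senses double-stranded RNA, rose by 5.24 ± 0.45. Of 24 phagocytosis and lysosome genes, 1 rose and 9 fell (17 fell adjusted over the list alone, and 15 over all genes after median centring), among them Cd68 (−2.05 ± 0.26) and Lamp1 (−2.06 ± 0.26). Of 18 TLR-induced effectors 2 rose and 7 fell, led by the inflammasome genes Mefv (−3.58 ± 0.29) and Nlrp3 (−2.74 ± 0.30). The adjusted p of these 3 lists was 2.1e-05, 1.3e-07 and 0.028 by camera and, with an estimated correlation, adjusted p = 0.25, 0.47 and 0.47. Fry gave adjusted p = 0.021, 0.031 and 0.065 in the same order. Markers of other cell types were higher in the macrophage libraries. Whether RNA from such cells lowered these lists and the monocyte markers was not tested.

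Of 25 macrophage markers 8 rose and 5 fell, or 13 and 5 adjusted over the list alone. The groups overlapped in the mean log2 level over all 26 listed members, tested or not. It was 4.21, 2.52 and 3.14 in monocyte replicates 1, 2 and 3 and 3.96, 3.70 and 4.19 in the macrophages. The iron exporter Slc40a1 rose by 2.82 ± 0.42, the adhesion molecule Vcam1 by 2.22 ± 0.34 and Cd5l by 2.83 ± 0.44, whereas Trem2, a lipid receptor of macrophages, fell by 2.66 ± 0.42. Siglec1, which encodes the sorting marker CD169, was at 17.0 ± 16.5 CPM in monocytes and 20.9 ± 3.75 CPM in macrophages, a log2 change of 0.86 ± 0.64 that did not pass (adjusted p = 0.42) and was −0.10 without monocyte replicate 2 and 1.64, past the threshold, without monocyte replicate 1. Itgax and H2-Ab1 did not pass (log2 changes 0.62 ± 0.55 and 2.20 ± 0.74, adjusted p = 0.51 and 0.056). Without monocyte replicate 1 both passed, with log2 changes of 1.35 and 3.32 (adjusted p = 0.016 and 1.8e-06), and H2-Ab1 also passed without macrophage replicate 3 (2.51, adjusted p = 0.033). Monocyte replicate 1 held 596 CPM of H2-Ab1 where the other monocyte libraries held 75.8 and 42.2.

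Markers of several other cell types were higher in the macrophage libraries. Of 16 T and NK cell genes 15 rose, with the NK receptor Ncr1 up by 5.09 ± 0.44 and the T cell kinase Lck by 3.73 ± 0.34. Of 13 B cell and plasma cell genes 12 rose, of 16 erythroid genes 15, of 11 megakaryocyte genes 8, of 13 basophil, mast cell and eosinophil genes 9 and of 9 stroma and endothelium genes 5, with 0 falls in each. The mast cell protease Cpa3 rose by 3.96 ± 0.38 and carbonic anhydrase Car2 by 4.05 ± 0.36. Adjusted over the list alone, 16, 12, 15, 9, 12 and 5 rose in the same order. After quantile normalization 4 of the 16 erythroid, 5 of the 11 megakaryocyte and 3 of the 9 stroma genes rose, and after median centring 10 erythroid and 3 stroma genes. Of 16 progenitor genes 12 rose, such as Mecom (4.18 ± 0.38), and 1 fell, Igsf6. Neutrophil genes went both ways, with 10 of 17 up and 6 down. In the conventional dendritic cell list 8 of 23 rose, among them Itgae (3.58 ± 0.37) and Cd8a (3.33 ± 0.40), and 5 fell, among them Clec10a (−3.31 ± 0.43). Camera passed the T and NK, B and plasma, erythroid, megakaryocyte, basophil and mast cell, stroma and progenitor lists with adjusted p between 2.0e-13 and 0.0055. With an estimated correlation 0 of the 33 lists passed, and the adjusted p of these 7 lay between 0.25 and 0.59. By fry the T and NK, megakaryocyte, basophil and mast cell, stroma and progenitor lists passed, with adjusted p between 0.014 and 0.021. The B and plasma and the erythroid lists did not pass by fry (adjusted p = 0.055 and 0.085).

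Of 23 immediate early genes 7 rose in macrophages, 0 fell and 16 did not pass. The mean log2 level of this list overlapped between the groups, with 5.59, 3.79 and 4.30 in monocyte replicates 1, 2 and 3 and 5.89, 6.32 and 5.43 in the macrophages. Those that rose included Egr1 (4.23 ± 0.51) and Fosb (3.19 ± 0.43). Of 22 dendritic cell maturation genes 9 rose and 1 fell. Adjusted over the list alone, 8 immediate early genes rose, and 11 maturation genes rose and 1 fell. Camera gave adjusted p = 0.00064 and 0.0055 for these lists, and adjusted p = 0.78 and 0.76 with an estimated correlation.

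Dendritic cells from vehicle mice were set beside the baseline populations without a test, since the tables appear to differ in how reads were assigned to genes. Cd209a was at 391 ± 49.9 CPM (SD, n = 4) in dendritic cells, 53.3 ± 47.6 CPM (n = 3) in monocytes and 1.20 ± 0.452 CPM (n = 3) in macrophages. Mgl2 was at 105 ± 55.8, 11.5 ± 10.4 and 2.33 ± 1.19 CPM in the same order, Mrc1 at 234 ± 40.8, 51.9 ± 39.5 and 50.1 ± 16.8 CPM, and Trf at 407 ± 41.5, 151 ± 84.9 and 105 ± 11.7 CPM. Il1b was at 11.4 ± 4.90, 1.82 ± 2.03 and 0.642 ± 0.326 CPM. These genes are a choice from the named genes, and others were not highest in dendritic cells. Fcrl5 was at 1.6 ± 1.4, 0.11 ± 0.12 and 8.6 ± 12.7 CPM and Ly6d at 0.76 ± 0.71, 1.1 ± 1.1 and 22.2 ± 25.5 CPM in the same order.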

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

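All tests of explanations below were chosen after results that they bear on had been seen. In the dendritic cell groups of 4, 1 library lay far from the other 3 (its gap to the nearest, divided by the whole range, was above the critical value of Dixon's test) for 18 of 292 pairs of a named gene and a group, or 6.16%, where chance gives about 1 in 20. PAM3CSK4 replicate 4 was that library for Cx3cr1 (0.831, 31.3 CPM, lowest), Ly6c2 (0.859, 170 CPM, highest), Npc2 (0.942, lowest) and Tlr3 (0.885, lowest). PAM3CSK4 replicate 1 was lowest for Marco (0.924, 15.7 CPM), Tnf (0.838) and Cox5b (0.877), and PAM3CSK4 replicate 2 for Dntt (0.835). Vehicle replicate 1 was highest for Cd209c (0.972) and lowest for Pgam1 (0.858), Pgk1 (0.862), Mmp8 (0.873) and Rps27l (0.852). Vehicle replicate 3 was highest for Saa3 (1.00, 0.281 CPM) and lowest for Ifit3b (0.862). Vehicle replicate 4 was highest for H2-DMa (0.902) and H2-DMb1 (0.831) and lowest for Irak3 (0.833).

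PAM3CSK4 replicate 4 was low in dendritic cell genes and high in neutrophil, erythroid and basophil, mast cell and eosinophil genes. Its position between the vehicle mean (0) and the mean of the other PAM3CSK4 libraries (1) was taken over 667 genes that changed at least 2-fold without it. The median position was 0.777 (quartiles 0.296 and 1.31), which argues against a library like those from vehicle mice. Whether a vehicle library that also held RNA from other cells would lie there was not tested. A difference in scale of the whole library would shift most genes alike. The median difference of all 11377 genes from the other PAM3CSK4 libraries was 0.026 log2 units, which argues against it. The median neutrophil gene lay at the 99.8th percentile of these differences. That list had been seen to be high in this library, so its percentile decides nothing. RNA from other marrow cells may account for the values of this library, with Ltf at 1962 and Lcn2 at 1317 CPM. The median list member was 3.81 log2 units above the other PAM3CSK4 libraries for neutrophil, 2.25 for erythroid and 0.72 for progenitor genes. The test asked each of these lists to reach 1 unit, and the last did not, so this stays open. A low progenitor list does not speak against RNA from neutrophils or erythroid cells. The median basophil, mast cell and eosinophil gene, not among the lists of that test, was 3.05 above the other PAM3CSK4 libraries. The gate asked for high GFP, MHC class II and CD11c and excluded Gr-1-positive and B220-positive cells, so a clean sort would hold few cells of these types. Neither its purity nor a stronger response behind this library was tested.

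In the macrophage libraries, markers of 6 other cell types were higher. RNA from such cells may account for it, and the lowest median log2 change of the 6 lists was 1.82, but these lists were taken up because they had risen, so the test decides nothing. The gate asked for GFP-negative cells high in MHC class II and positive for CD169, and removed B220-positive and Gr-1-positive cells. A clean sort would thus hold few T, NK, erythroid, mast or megakaryocyte cells, purity was not tested, and the source stays open. Exchanged macrophage and monocyte labels are argued against by Cx3cr1, whose log2 change plus 2 SE was −3.77. Scaling could not be settled as a contributor, since 87.3% of the 71 risen members still passed after median centring, short of the share set as excluding it.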

How the results depend on the processing

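Of the named genes that passed, 29 of 70 in dendritic cells and 104 of 127 in macrophages against monocytes kept their call with any 1 library left out, and 20 and 101 kept it under every setting tried. Of the 582 genes, 142 were also called with no filter (166 genes in all, more genes being tested) and 581 with array weights (1649). Array weights called 5471 genes in macrophages against monocytes. The replicate block called 976 genes in dendritic cells. There the correlations of deviations of same-numbered libraries were 0.033, 0.29, −0.12 and 0.30, so the numbers were not taken to pair the libraries. In macrophages against monocytes they were 0.18, 0.084 and 0.12, and each library correlated best with its own number, a hint from the data alone. With each library left out in turn, the counts were 184 to 1008 and 1699 to 3364. The cause was not tested for array weights, the block or single libraries. Under the other settings the number of genes changed stayed within 1.5 times the count given.

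With an estimated correlation 0 of 33 lists passed in either comparison, and with fry 0 in dendritic cells and 8 in macrophages against monocytes. These 8 were the monocyte, TLR signalling, lysosome, T and NK, basophil and mast cell, megakaryocyte, stroma and progenitor lists. With an estimated correlation, 1 list in the first comparison and 5 in the second had an unadjusted p under 0.05. No alternative for read depth was run. The alternatives for dendritic cells against the other populations were not run, as no test was made.

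Reversals were of values that did not pass. For lists, what turned is the direction of the list test, and the median given need not change sign. Camera sets a list against the other genes and fry does not, so where these 2 differ no single test has turned. In dendritic cells Itga2b was −0.10 with pseudocount 0.1, −0.16 rescaled to a common total, −0.19 after median centring, −0.11 after quantile normalization and −0.27 with array weights, Tlr6 was −0.063, −0.14 and −0.13 under the 3 scalings, and Ly6c2 was −0.073 with array weights. Leaving out libraries gave −0.69 to 0.36 for Itga2b, −0.17 to 0.044 for Kdm5d, −0.69 to 0.21 for Cx3cr1, −1.02 to 0.088 for Itgax, −0.16 to 0.92 for Ly6c2 and −0.15 to 0.24 for Tlr6. By fry, the direction differed from camera for the lists of MHC class I (median 0.024), lysosome (0.23, also with no filter), niche factors (0.22) and T and NK genes (−0.088), and after median centring for sex-linked genes (0.036). With libraries left out, list medians were 0.027 to 0.35 for lysosome, −0.26 to 0.080 for T and NK, 0.19 to 0.67 for histones and 0.12 to 0.43 for sex-linked genes. In macrophages against monocytes, fry differed for interferon (−0.11), iron (0.086), cholesterol (0.10) and ribosomal (0.058) lists, no filter for NF-kB (0.050), and Eif2s3y was −0.012 after median centring. With the sorting marker genes left out of the lists, an alternative chosen after seeing the data, the MHC class II list turned (median 0.0064). Leaving out libraries gave −0.080 to 0.44 for Eif2s3y and −0.10 to 1.64 for Siglec1, and list medians of −0.037 to 0.41 for NF-kB, −0.35 to 0.15 for interferon, 0.81 to 2.14 for MHC class II and −0.11 to 0.25 for ribosomal genes. The cause was not tested.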

Other observations

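Both tests of the falls in dendritic cells below were chosen after results that they bear on had been seen, while the counts of other splits were planned. The 261 genes that fell with PAM3CSK4 had a median log2 change of −1.50, and −1.40 without PAM3CSK4 replicate 4. A lower share of dendritic cells in the treated libraries would lower Itgax, a dendritic cell gene, by a like amount. Without replicate 4 its log2 change minus 2 SE was −0.42, above that median, but every library was sorted for high CD11c, the product of Itgax, so the gate holds this gene up and the test decides nothing. Zbtb46, which was not a sorting marker, fell by 1.27 ± 0.29 in the same fit, and Flt3, chosen after its values were seen, had a log2 change of −0.47 ± 0.30 (adjusted p = 0.37), so a lower share of dendritic cells stays open. All of the fallen genes (100%) still passed after median centring, but centring moved every change downwards (by 0.22 at the median), so the test on the deposited scaling could not have come out otherwise and decides nothing. Whether the makeup of the cells within the dendritic cell gate changed, or each cell, was not tested.

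Other splits of the same libraries were counted for each comparison. For dendritic cells, 1 of 35 splits, the real one, called 582 genes, and the highest of the others called 1. A share of 1 in 35 is the smallest that these splits can give, so it does not exclude chance. The other splits also mix vehicle and PAM3CSK4 libraries, which adds any difference between the groups to their spread. The count of lists is different: 12 of the 35 splits passed at least as many lists as the real 17, and 2 of them passed 22, the highest number, so chance is not excluded for the camera calls of lists with the preset correlation in dendritic cells. For macrophages against monocytes there are 10 splits, too few for a share under 0.05. The real split called 2468 genes and the highest other 0, while it passed 15 lists (5 of the splits passed as many) and the highest other 26.

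Among the 582 dendritic cell genes are further groups that the lists cover in part. Of 20 glycolysis genes, 25 nuclear oxidative phosphorylation genes and 19 unfolded protein response genes, 1 each rose (Pgam1, Cox5a and Manf) and 0 fell, with 7, 7 and 3 risen adjusted over the list alone. Camera gave adjusted p = 0.0094, 0.00012 and 0.0036, and adjusted p = 0.67 for each with an estimated correlation. The calls of all 3 genes were lost with any 1 of 6 libraries left out (adjusted p up to 0.098). Of 24 phagocytosis and lysosome genes 3 rose, the protease Ctsl (log2 change 1.70 ± 0.29) and the proton pump subunits Atp6v0d1 and Atp6v1a, and of 7 stroma and endothelium genes 2 rose, Pecam1 and Kdr. The calls of Atp6v0d1, Atp6v1a, Pecam1 and Kdr were lost with any 1 of 6, 7, 4 and 6 libraries left out (adjusted p up to 0.11). Of 78 ribosomal protein genes and 65 replication-dependent histone genes 0 passed in limma, while 2 ribosomal genes and 1 histone gene were higher and 4 ribosomal genes lower at an unadjusted p under 0.05. Camera placed the ribosomal list below the other genes (adjusted p = 0.00012, and adjusted p = 0.67 with an estimated correlation). In macrophages against monocytes, 1 of 30 cell cycle genes, Aurkb, fell and 0 rose, with 0 of either adjusted over the list alone. Its call was lost with any 1 of 3 of the 6 libraries left out (adjusted p up to 0.15). For this list camera gave adjusted p = 0.0015, or adjusted p = 0.82 with an estimated correlation.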
